A study of Escherichia coli with 21 samples.

How the data were processed

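The series holds 21 two-colour arrays of RNA from Escherichia coli MG1655. Per the labels, the bacteria grew in a glycerol-limited chemostat built without metal parts, in a medium with no added zinc. Zinc sulfate was then added, in an amount not used here because the unit in the labels is in doubt, to one culture and water to a control culture, and both were sampled at 0 min, just before the addition, and then at 2.5 min, 7 min, 10 min and 30 min. Each array carries RNA of the zinc culture against RNA of the water culture taken at the same time. At each of the 5 times there are slides with the letters A and B, each letter with both dye orientations; letter A at 10 min has 3 slides. The labels do not say whether A and B are separate cultures or repeated work on the same cultures, so p-values here measure only the spread between these samples.

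The values are log2 ratios of both channels of one array, as deposited, taken from the series' value table alone; the scanner, the background correction, the normalization and the filter on spots are not given in the sources used here. Base 2 is an assumption: the largest absolute value, 11.9, would be a ratio of 147000 as a natural logarithm, beyond the highest scanner value of 65535, and a ratio of 3816 as log2. Array medians lay between -0.0798 and 0.0394 and array standard deviations between 0.662 and 1.04. The table gives ratios only, so signal over background is unknown, and only the number of arrays and the spread between arrays and replicates describe the precision.

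Whether the dye-swapped arrays had already been turned to one direction was to be read from the correlation, across genes, between arrays of opposite orientation at one time, with a value below 0 meaning not turned. That rule did not settle it: 6 of the 10 correlations were below 0, from -0.0806 to -0.428, and 4 were above 0, namely 0.306 and 0.435 for letters A and B at 0 min, 0.189 for B at 2.5 min and 0.0499 for A at 7 min. This is a departure from the plan. After the values had been seen, the 0 min array of the same letter and orientation was subtracted first; the correlations at later times were then all below 0, from -0.249 to -0.652, and the arrays were read as not turned. The direction of the ratio is likewise not given in the sources used here. It was set to the one that places zntA, a zinc efflux gene induced by zinc, higher after zinc, as planned. This made the deposited values Cy3 over Cy5, so the sign was changed for arrays with zinc in Cy5, whereas the plan had written of changing those with zinc in Cy3. The direction is therefore likely, zntA is no independent evidence for it, and every direction given here would turn together if it were wrong. Reading the arrays as already turned was added as an alternative after the values had been seen.

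Of the 4608 features in the table, 4319 had a value on at least 1 array and 4318 on all 21. Names came from the feature table and the gene table of assembly ASM584v2, which was used for names and neighbours only: 4074 features had 1 gene symbol, 245 had none and 0 had several, and 197 symbols were updated through the gene identifier. Features of the 47 symbols present more than once were averaged, and a gene was tested when all 10 replicate means had a value, which left 4271 genes or unnamed features. Arrays of one letter and time were averaged within each dye orientation and then over both orientations, so that n = 2 per time.

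Differences were tested with limma 3.58.1 in R 4.3.3, with statmod 1.5.0, in one fit with a mean per time (lmFit and eBayes, without trend, not robust). The spread was shared over times, with 5 residual degrees of freedom, 5.57 prior degrees of freedom and a prior variance of 0.104. The comparisons were zinc against water at each time, the change of that ratio from 0 min to each later time, and a moderated F test over the 4 changes. P-values were adjusted by the Benjamini-Hochberg method over the 4271 tests of a comparison, with a threshold of 0.05, and all tests were two-sided. The words rose and fell stand for a zinc over water ratio above or below 1 that passed this threshold. They describe a difference between the cultures at one time unless a change from 0 min is named.

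A set of 24 gene lists with 516 genes, 507 of them measured, was written before the data were examined, as were the comparisons, the rule for named genes and all alternatives not said to be added later. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, each adjusted over the 24 lists of a comparison. Counts of list members were also adjusted over the list alone. The lists cover the Zur regulon, zinc export and zinc-responsive genes, copper and silver homeostasis, the Fur regulon, the SoxRS and OxyR regulons, Suf and Isc iron-sulfur cluster assembly, heat shock, envelope stress, acid resistance, the general stress response, and cysteine, methionine, arginine, histidine and nucleotide synthesis. They also cover flagella and chemotaxis, ribosomal proteins, NADH dehydrogenase I with ATP synthase, the tricarboxylic acid cycle, glycerol use, the Pho regulon, transport of manganese, nickel, cobalt, magnesium and potassium, and anaerobic respiration and fermentation.

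The rule for named genes took every measured member of the Zur and zinc export lists; at each later time the 8 genes with the largest positive and the 8 with the largest negative mean among those past the threshold with the same sign in both replicates; up to 4 members with the smallest p of every other list past the camera threshold; at 0 min, where no gene passed, the 3 with the smallest p in each direction; and the 10 with the smallest F test p. Unnamed features are given by their identifier. Any gene named outside this rule is said to have been chosen after its values were seen.

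The procedure was tested on simulated data in 20 runs with 200 of 4271 genes changed at 30 min. For zinc against water at 30 min it recovered 6%, 57.9%, 94.1% and 99.9% of genes changed by 0.5, 1, 2 and 4 on the log2 scale. For the change from 0 min to 30 min the shares were 1.4%, 23.1%, 78.8% and 99.3%, and for the F test 0.3%, 8.3%, 70.2% and 98%. Of the calls, 4.97%, 5.19% and 4.64% were false in these comparisons, with 0 calls at a time without simulated change. Of 480 tests of unchanged lists 0 were called, and a list shifted by -1 was called in 20 of 20 runs. The simulated values were drawn independently for each gene, and the simulated lists were random genes. The runs therefore do not measure how often a list of genes that vary together is called falsely. Replicates and times were drawn independently as well. The shares of false calls thus do not cover replicates from the same cultures or repeated sampling of a culture.

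The alternatives tried were subtracting array medians; scale and quantile normalization between arrays; each array as an observation with letter within time as a random block; a single dye orientation; a plain mean over the arrays of a letter; letter as a fixed block; each time fitted alone; a variance prior with trend, robust; each feature by itself; other filters on missing values; other thresholds; each replicate left out; an estimated correlation and fry for lists; and the sign turned. Added after the data had been seen were the dye swaps read as already turned, 3 slides left out in turn (A2 and A3 at 10 min, B1 at 30 min), and letters as labelled or crossed between 0 and 10 min. No sample of the series was left out of the main comparisons.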

Results

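Transcript levels of a zinc-starved Escherichia coli MG1655 culture given zinc were compared with those of a culture given water on 21 two-colour arrays, to follow the passage from zinc starvation to what the labels call surfeit. The amount of zinc added is not used here, because the unit of the concentration in the labels is in doubt. There were 4 arrays at 0, 2.5, 7 and 30 min and 5 at 10 min, averaged to replicates A and B (n = 2) at each time. Values are mean log2 ratios of zinc over water ± SD of both replicates. The 4271 genes or unnamed features were tested with limma, and each gene called at any time had the same sign in both replicates. Correlations between replicates, across genes that are not independent of each other, were 0.136 at 0 min, 0.413 at 2.5 min, 0.602 at 7 min, 0.657 at 10 min and 0.73 at 30 min. Base 2 and the direction of the ratio rest on assumptions given with the processing.

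Before the addition, at 0 min, the cultures were compared to give the background against which later values are read. limma called 0 genes, with 213 at an unadjusted p under 0.05 against 214 by chance. The genes with the smallest p did not pass. Nearest among the higher were yhhZ (1.42 ± 0.768), adk, for adenylate kinase (0.81 ± 0.147), and bamC (0.76 ± 0.170). Among the lower these were the unnamed feature 1.2.6.4 (-1.50 ± 0.0256, adjusted p = 0.0616), cysH (-1.27 ± 0.426) and ycfK (-0.84 ± 0.0737). zntA stood at -0.17 ± 0.0213 and zinT at 0.18 ± 0.219.

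Camera called 5 of the 24 lists at 0 min, in which 0 members passed, over all genes or adjusted over the list alone. Nucleotide synthesis was higher (median 0.57, 21 measured; purM 2.06 ± 0.674, pyrF 1.11 ± 0.564), as were ribosomal proteins (0.24, 54 measured; rpsB 0.63 ± 0.314) and glycerol use (0.22, 12 measured; glpB 1.33 ± 1.51, glpG 0.61 ± 0.338). The general stress response (-0.17, 21 measured; rpoS -0.60 ± 0.0825, sodC -0.49 ± 0.140) and heat shock genes (-0.19, 19 measured; groL -0.64 ± 0.373) were lower. Each call was lost with an estimated correlation (adjusted p = 0.651 for nucleotide, ribosomal, glycerol and heat shock lists and 0.807 for general stress). Without replicate B the medians were 0.135, 0.116, 0.0489, -0.0458 and -0.0554 in the order given and none passed. With zinc in Cy3 alone none of the 5 passed and 155 genes were called, and with zinc in Cy5 alone the nucleotide and glycerol lists passed and 10 genes were called. In a single orientation an effect of the dye on a gene cannot be told from a difference between the cultures. As deposited, arrays of opposite orientation correlated above 0 at 0 min (0.306 for A and 0.435 for B). The arginine list went opposite ways in replicates A (-0.704) and B (0.781) and did not pass with both, though it did with either alone.

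At 2.5 min, 36 genes differed between zinc and water, 27 higher and 9 lower. Of these zntA, for the zinc efflux ATPase, rose most (3.36 ± 0.155, adjusted p = 0.000264). Genes of zinc uptake fell: znuC by 1.87 on the log2 scale (SD 0.228) and znuB by 0.95 (SD 0.0375), both of the ATP-dependent zinc importer. Higher genes included degP, a periplasmic protease and chaperone (2.81 ± 0.0890), arnB, of lipid A modification (2.97 ± 0.407), yncJ (2.62 ± 0.366), ldtC (2.35 ± 0.282), mutL, of mismatch repair (2.58 ± 0.172), and the unnamed features 3.1.13.12 (3.09 ± 1.10) and 2.1.13.12 (2.64 ± 0.706). Lower genes included bfd, for bacterioferritin-associated ferredoxin (-3.44 ± 0.116), the unnamed feature 4.1.3.15 (-3.35 ± 0.540), yrbL (-1.53 ± 0.450), cysH (-1.50 ± 0.234), the curli genes csgE (-1.39 ± 0.600) and csgF (-1.14 ± 0.0270), and ybaN (-1.03 ± 0.152). The value of cysH had been -1.27 at 0 min and its change from 0 min did not pass (-0.23).

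Of 6 measured Zur regulon genes, 2 fell and 4 did not pass at 2.5 min, with 5 lower when adjusted over the list alone (median -1.03). Of 15 zinc export genes only zntA rose, 3 when adjusted over the list alone. This list did not pass (camera adjusted p = 0.125), with a median of -0.00 against a mean of 0.39. Of 15 envelope stress genes 5 rose, 11 adjusted over the list alone (median 1.16). The 5 were degP, fkpA (1.28 ± 0.0253), ppiA (1.15 ± 0.161), yccA (1.64 ± 0.607) and rseB (1.58 ± 0.0196, chosen after its values were seen, its call lost without replicate A, 1.60, or B, 1.57). Of 45 Fur regulon genes only bfd fell, 17 adjusted over the list alone (median -0.56). The values of other members were close to the threshold: nrdH stood at -1.70 ± 0.0813, nrdI at -1.46 ± 0.329 and exbB at -1.38 ± 0.239 without passing. Of 11 copper genes only cueO rose (1.27 ± 0.156), 3 adjusted over the list alone (median 0.43; copA 1.69 ± 0.857, not passed). The general stress list (median -0.34; csgD -1.63 ± 0.102), the nucleotide list (0.31) and the ribosomal list (0.11) also passed camera with 0 members past the threshold over all genes. Adjusted over the list alone, 1 general stress gene was lower and 0 of the others passed. With an estimated correlation 0 of these 7 calls remained. The adjusted p was then 0.281 for Zur, 0.0936 for envelope stress, 0.0651 for Fur, 0.412 for copper, 0.605 for general stress, 0.691 for nucleotide and 0.636 for ribosomal genes. With zinc in Cy5 alone the copper list was at -0.147 and did not pass. With zinc in Cy3 alone the ribosomal list was at -0.0461 without passing and zinc export passed (0.667). The general stress, nucleotide and ribosomal lists passed in neither orientation.

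The count at 2.5 min was 14 without replicate A and 10 without replicate B, and in each case 15 of the 22 calls among named genes were lost; zntA, mutL, ldtC, bfd and 4.1.3.15 kept theirs both times, while znuC stood at -2.04 and -1.71, degP at 2.75 and 2.88 and arnB at 2.68 and 3.26 without passing. Without replicate A the medians of the copper (0.119), nucleotide (0.191) and ribosomal (0.0675) lists no longer passed, and the count was 172 with zinc in Cy5 alone, 194 with zinc in Cy3 alone, 69 with scale and 81 with quantile normalization, 92 with each array as an observation, 195 when the time was fitted alone and 16 with a trended, robust variance prior.

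At 7 min, 259 genes differed, 175 higher and 84 lower, and genes of copper resistance were among the highest. Of these cusC, of the copper and silver efflux pump, stood at 5.91 ± 0.669, copA, for the copper efflux ATPase, at 5.04 ± 0.148 and cueO, for the periplasmic copper oxidase, at 4.26 ± 0.0511. The others of the 8 highest were degP (5.33 ± 0.384), yncJ (4.84 ± 0.153), cspI, a cold shock family gene (4.56 ± 0.521), spy, for a periplasmic chaperone (4.33 ± 0.343), and ais (4.21 ± 0.0919). The lowest were ykgM, for a zinc-independent ribosomal protein paralogue (-3.51 ± 0.313), the porin gene nmpC (-3.47 ± 0.571), 4.1.3.15 (-3.34 ± 0.0444), csgE (-3.23 ± 0.359), ompA, for an outer membrane protein (-2.85 ± 0.0635), ychH (-2.85 ± 0.141), fhuF, of iron acquisition (-2.72 ± 0.321), and yrbL (-2.64 ± 0.135).

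All 6 measured Zur regulon genes fell at 7 min, also when adjusted over the list alone (median -1.94): znuA (-1.54 ± 0.0123), znuB (-1.35 ± 0.137), znuC (-2.09 ± 0.343), zinT, for a periplasmic zinc-binding protein (-2.45 ± 0.290), ykgM and pliG (-1.80 ± 1.39). The call was lost with an estimated correlation (adjusted p = 0.0805). Of 15 zinc export genes 5 rose, 6 adjusted over the list alone (median 0.48; adjusted p = 0.0313 with an estimated correlation). The 5 were zntA (4.13 ± 0.550), spy, zraP, for a zinc-binding periplasmic protein (2.49 ± 0.107), and mdtA (2.26 ± 0.365) and mdtD (1.02 ± 0.132) of a multidrug efflux operon. With zinc in Cy5 alone this list was at 0.0122 without passing and mdtD at -0.00159.

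Of 11 copper genes 9 rose at 7 min and 2 did not pass, 10 rising adjusted over the list alone (median 3.03; adjusted p = 0.0301 with an estimated correlation). They included cusF (3.84 ± 0.135) and cusB (3.20 ± 0.159), while cusA stood at 0.23 ± 0.317. Of 15 envelope stress genes 13 rose, also over the list alone (median 1.70; adjusted p = 0.0366 with an estimated correlation). Examples were dgcZ (3.06 ± 0.360), ppiA (1.76 ± 0.102) and srkA (1.73 ± 0.0926). Of 45 Fur regulon genes 21 fell and 0 rose, 26 and 1 adjusted over the list alone (median -0.93; adjusted p = 0.0301 with an estimated correlation). The lower ones included bfd (-2.26 ± 0.603), yncE (-2.20 ± 0.207), and exbB (-2.12 ± 0.418) and exbD (-1.92 ± 0.139) of the TonB energy-transfer complex. Of 19 heat shock genes 7 rose, 15 adjusted over the list alone (median 0.81; adjusted p = 0.0419 with an estimated correlation). Higher members were htpX (2.84 ± 0.293), rpoH, for the heat shock sigma factor (1.59 ± 0.578), htpG (1.13 ± 0.179) and dnaJ (1.10 ± 0.198).

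At 7 min 5 further lists passed camera in the lower direction, and each was lost with an estimated correlation. In the general stress list 2 of 21 genes fell and 1 rose, 3 and 1 adjusted over the list alone (median -0.37, adjusted p = 0.516 with an estimated correlation). Here csgD (-2.63 ± 0.850) and osmE (-0.82 ± 0.0508) fell and osmB rose (1.01 ± 0.625). In the glycerol list 1 of 12 fell, glpF (-0.73 ± 0.129), 3 adjusted over the list alone (median -0.58, adjusted p = 0.516). No member passed in the tricarboxylic acid cycle (median -0.30, adjusted p = 0.598; sdhC -1.41 ± 0.165, 2 lower adjusted over the list alone), in NADH dehydrogenase I with ATP synthase (-0.29, adjusted p = 0.336; atpF -0.88 ± 0.326, 0 over the list alone) or in nucleotide synthesis (-0.62, adjusted p = 0.598; pyrC -1.17 ± 1.50, 0 over the list alone). For nucleotide synthesis replicate A gave -1.5 and replicate B 0.166. With zinc in Cy3 alone the NADH dehydrogenase and ATP synthase list was at 0.223 without passing. With zinc in Cy5 alone the general stress (-0.291), glycerol (-0.331) and tricarboxylic acid (-0.121) lists did not pass.

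The count at 7 min was 125 without replicate A and 139 without replicate B, and 22 and 24 of the 68 calls among named genes were lost, including those of ykgM (-3.73 and -3.29), znuA (-1.53 and -1.55), mdtD (0.925 and 1.11), dnaJ (0.96 and 1.24), htpG (1.01 and 1.26), osmE (-0.785 and -0.857), glpF (-0.639 and -0.821) and fhuF (-2.95 and -2.50) in both cases, zinT (-2.24), osmB (0.563) and exbB (-1.82) without A and pliG (-0.814) and rpoH (1.18) without B. Without replicate A the glycerol (-0.156) and tricarboxylic acid (-0.227) lists no longer passed and the nucleotide list turned to 0.166, without replicate B the general stress list (-0.295) no longer passed, and the count was 739 with zinc in Cy5 alone, 924 with zinc in Cy3 alone and 402 with each array as an observation.

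At 10 min, 502 genes differed, 273 higher and 229 lower. The copper efflux genes cusC (6.60 ± 0.437), cusF (4.88 ± 0.238) and cusB (4.77 ± 0.0469), copA (4.64 ± 0.838), degP (5.05 ± 0.995), yncJ (5.04 ± 0.0550), zntA (4.67 ± 0.0565) and spy (4.65 ± 0.609) were highest. ykgM (-4.73 ± 1.69), zinT (-4.39 ± 1.03), the porin genes ompF (-3.86 ± 0.508) and nmpC (-3.38 ± 1.00), 4.1.3.15 (-3.43 ± 0.315), aroF, of aromatic amino acid synthesis (-3.43 ± 1.56), yjcH (-3.27 ± 1.61) and pgaA (-3.18 ± 0.892) were lowest.

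All 6 Zur regulon genes fell at 10 min, also adjusted over the list alone (median -2.83; adjusted p = 0.0702 with an estimated correlation, so the call was lost). At this time znuA stood at -2.03 ± 0.184, znuB at -1.42 ± 0.0305, znuC at -2.74 ± 0.341 and pliG at -2.91 ± 0.919. Of 15 zinc export genes 7 rose, 7 adjusted over the list alone with 1 lower (median 0.48; adjusted p = 0.033 with an estimated correlation). Added to those of 7 min were mdtB (1.40 ± 0.462) and mdtC (1.99 ± 0.301), with zraP at 3.30 ± 0.874. Of 11 copper genes 10 rose, also over the list alone (median 2.83; adjusted p = 0.033 with an estimated correlation). Now cusA stood at 2.83 ± 0.816 and cueO at 3.81 ± 0.387. Of 15 envelope stress genes 12 rose, 14 adjusted over the list alone (median 1.59; adjusted p = 0.0364 with an estimated correlation; dgcZ 3.98 ± 0.844, srkA 1.75 ± 0.411).

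Of 19 heat shock genes 15 rose at 10 min, 18 adjusted over the list alone (median 1.02; adjusted p = 0.033 with an estimated correlation). These included htpX (2.87 ± 0.443), the protease genes hslU (1.77 ± 0.0417) and hslV (1.46 ± 0.0501) and the chaperone gene dnaK (1.57 ± 0.253). Of 45 Fur regulon genes 16 fell and 1 rose (fecC, 0.88 ± 0.213, chosen after its values were seen, lost without replicate A, 0.728, or B, 1.03), 24 and 1 adjusted over the list alone (median -0.78; adjusted p = 0.033 with an estimated correlation). Lower members were bfd at -2.97 ± 0.294, exbD at -2.59 ± 0.358, exbB at -2.49 ± 0.180 and entE, of enterobactin synthesis, at -1.88 ± 0.551. Of 21 general stress genes 12 fell and 1 rose, 17 and 1 adjusted over the list alone (median -0.95; adjusted p = 0.233 with an estimated correlation). Examples were osmE (-1.89 ± 0.0840), csgD (-2.57 ± 0.373) and osmY (-1.36 ± 0.283) among the lower and osmB (0.95 ± 0.181) as the one that rose. Of 16 acid resistance genes 6 fell and 1 rose (adiY, 0.69 ± 0.131, chosen after its values were seen, lost without replicate A, 0.599, or B, 0.785), 6 and 2 adjusted over the list alone (median -0.62; adjusted p = 0.34 with an estimated correlation). Lower ones were ymgA (-1.76 ± 0.0140), hdeD (-1.14 ± 0.224). Of 19 tricarboxylic acid cycle genes 4 fell, 5 adjusted over the list alone (median -0.48; adjusted p = 0.411 with an estimated correlation). The 4 were fumC (-1.70 ± 0.868), sdhB (-1.49 ± 0.454), fumA (-1.08 ± 0.214), acnA (-0.86 ± 0.00589). Of 14 Suf and Isc genes 8 rose and 3 fell at 10 min, 8 and 5 adjusted over the list alone (median 1.22). The 3 that fell were sufA (-1.4), sufB (-1.06) and sufC (-0.927) of the Suf system. Among the 8 that rose were iscU (1.46), hscA (1.43) and fdx (1.29) of the Isc system. All of these were chosen after their values were seen. Calls of sufB (-1.13 and -0.987), sufC (-0.975 and -0.88) and iscU (1.5 and 1.41) ended without replicate A or B. Those of hscA (1.19) and fdx (0.749) ended without A, and sufA without B (-1.05). The list as a whole did not pass camera (adjusted p = 0.0803) but passed fry (adjusted p = 0.00977). It passed camera with each array as an observation (adjusted p = 0.000775), with zinc in Cy3 alone (0.00228), with a plain mean over the arrays of a letter (0.0430) and without replicate B (0.0442).

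In 3 biosynthetic lists that passed at 10 min the calls were also lost with an estimated correlation. Of 7 histidine genes 4 rose, 6 adjusted over the list alone (median 1.50, adjusted p = 0.338). The 4 were hisA (1.75 ± 0.824), hisC (1.73 ± 1.56), hisH (1.65 ± 1.05) and hisF (1.50 ± 1.51), and the list's median was 2.34 in replicate A and 0.431 in replicate B. Of 15 methionine genes only metE fell, for the cobalamin-independent methionine synthase (-1.96 ± 0.768), also over the list alone (median -0.49, adjusted p = 0.411). Of 54 ribosomal protein genes only rplV rose (0.83 ± 0.434), 0 adjusted over the list alone (median 0.26, adjusted p = 0.295). With zinc in Cy5 alone the acid resistance (-0.367), methionine (-0.311) and tricarboxylic acid (-0.43) lists did not pass at 10 min.

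The count at 10 min was 290 without replicate A and 229 without replicate B, and 28 and 26 of the 99 calls among named genes were lost, among them those of aroF (-2.32 and -4.54), sdhB (-1.17 and -1.81), fumA (-0.933 and -1.24), acnA (-0.858 and -0.866), osmB (0.817 and 1.07) and rplV (0.522 and 1.14) in both cases, mdtB (1.07), fumC (-1.08), hdeD (-0.978), hisA (1.17), hisC (0.624), hisH (0.907), hisF (0.431) and osmY (-1.16) without A and mdtD (0.729) without B. The histidine list no longer passed without A (0.431) nor acid resistance without B (-0.352), yjcH stood at -2.14 without A, and the count was 142 when the time was fitted alone and 976 with each array as an observation.

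At 30 min, 446 genes differed, 204 higher and 242 lower. The highest means were those of yebE (6.37 ± 3.46), cusC (6.13 ± 0.00538), cusF (5.60 ± 0.325), spy (5.15 ± 0.672), yncJ (5.08 ± 1.69), cusB (5.01 ± 0.0938), degP (4.62 ± 1.84) and cusA (4.46 ± 0.00430). The place of yebE rests on replicate B, since it stood at 3.92 without B and 8.81 without A. The lowest were zinT (-6.18 ± 1.19), ykgM (-5.88 ± 1.40), ompF (-4.50 ± 0.999), pliG (-3.78 ± 0.169), pgaA (-3.48 ± 1.06), nmpC (-3.40 ± 0.206), yjcH (-3.40 ± 1.08) and ydjG (-3.17 ± 0.556). Still higher with zinc were copA (2.50 ± 1.27) and cueO (1.21 ± 0.0377), while bfd stood at -0.33 ± 0.249 without passing.

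All 6 Zur regulon genes remained lower at 30 min, also adjusted over the list alone (median -3.04; adjusted p = 0.0694 with an estimated correlation, so the call was lost). By then znuA stood at -1.85 ± 0.936, znuB at -1.41 ± 0.0176 and znuC at -2.30 ± 0.310. Of 15 zinc export genes 8 rose, 9 adjusted over the list alone (median 0.86; adjusted p = 0.0528 with an estimated correlation, so the call was lost). The 8 were zntA (4.04 ± 0.933), zraP (3.78 ± 0.931), spy, mdtA (1.75 ± 0.271), mdtB (0.92 ± 0.579), mdtC (1.61 ± 0.674), mdtD (1.38 ± 0.248) and baeS (0.86 ± 0.350). The members that did not pass at any time were zntR, zitB, fieF, zraS, zraR, zupT and baeR, at -0.02, 0.17, -0.40, 0.24, 0.19, -0.14 and 0.72 at 30 min. Of 11 copper genes 8 rose, 9 adjusted over the list alone (median 2.94; adjusted p = 0.0528 with an estimated correlation). Of 15 envelope stress genes 11 rose, 14 adjusted over the list alone (median 1.30; adjusted p = 0.0638 with an estimated correlation; dgcZ 3.49 ± 1.01, dsbA 1.98 ± 0.287).

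Of 14 Suf and Isc genes 8 rose at 30 min, also over the list alone (median 1.02; adjusted p = 0.0638 with an estimated correlation). These 8 all belong to the Isc system of iron-sulfur cluster assembly, and no Suf gene was among them. The rule for named genes took iscR (1.19 ± 0.334), iscS (1.35 ± 0.208), hscB (1.05 ± 0.351), iscX (1.25 ± 0.659) and iscA. The others, chosen after their values were seen, were iscU (1.06), hscA (0.982) and fdx (1.06). Calls of hscA (1.1 and 0.86) and fdx (1.22 and 0.894) ended without replicate A or B, and that of iscU without B (0.579). Of 13 arginine genes 3 rose, 6 adjusted over the list alone (median 0.86; adjusted p = 0.349 with an estimated correlation). The 3 were argE (1.36 ± 0.374), artJ (0.88 ± 0.0846) and argI (1.37 ± 0.301). Of 54 ribosomal protein genes 2 rose, rpsR (0.82 ± 0.325) and rplI (0.84 ± 0.165), 0 adjusted over the list alone (median 0.20; adjusted p = 0.303 with an estimated correlation).

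Several lists of stress and energy metabolism were lower at 30 min, and each call was lost with an estimated correlation. Of 21 general stress genes 11 fell and 1 rose, 15 and 1 adjusted over the list alone (median -1.04, adjusted p = 0.176; csgD -2.95 ± 0.741, osmY -1.88 ± 0.431, and osmB, higher, 1.18 ± 0.0815). Of 16 acid resistance genes 8 fell, also over the list alone (median -0.91, adjusted p = 0.176; gadB -2.09 ± 0.525, hdeA -1.86 ± 0.901). Of 19 tricarboxylic acid cycle genes 6 fell, 10 adjusted over the list alone (median -0.74, adjusted p = 0.349; sdhB -1.82 ± 0.613, fumA -1.30 ± 0.0394). Of 22 genes of NADH dehydrogenase I with ATP synthase 3 fell, 4 adjusted over the list alone (median -0.43, adjusted p = 0.176; nuoE -0.86 ± 0.123, nuoF -0.81 ± 0.380, nuoL -0.70 ± 0.291). Of 12 glycerol genes 2 fell, 4 adjusted over the list alone (median -0.54, adjusted p = 0.303; glpT -2.56 ± 0.878, glpF -0.72 ± 0.187). Of 13 OxyR genes 2 fell, also over the list alone (median -0.24, adjusted p = 0.176; dps -1.29 ± 0.532, yaaA -0.85 ± 0.105). Of 15 methionine genes 1 fell, also over the list alone, and the list did not pass (median -0.44, adjusted p = 0.0539). It passed with each array as an observation (0.0223), letter as a fixed block (0.0258), the time alone (0.00153), zinc in Cy3 alone (0.0320) or slide B1 left out (0.0183). The Fur list (median 0.09, 0 of 45 past the threshold; 0.225 and past it without replicate B) and the heat shock list (median 0.01, htpX at 2.44 ± 0.456 and rpoH at 1.07 ± 0.00381 the 2 that rose) did not pass. With zinc in Cy5 alone the OxyR list (0.113) and yaaA (0.192) stood above 0 and rpsR below (-0.0559), and the Suf and Isc (1.24) and glycerol (-0.547) lists did not pass. With zinc in Cy3 alone acnA (0.0409), nuoE (0.064), nuoF (0.141) and nuoL (0.22) stood above 0, as did the NADH dehydrogenase and ATP synthase list (0.073). The OxyR (-0.354) and ribosomal (0.179) lists did not pass in Cy3 alone.

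The count at 30 min was 106 without replicate B, which ended 47 of the 85 calls among named genes against 23 without replicate A, among them copA (1.60), cueO (1.19), znuA (-1.19), mdtB (0.512), mdtC (1.13), mdtD (1.20), yjcH (-2.63), ydjG (-2.77), fumC (-1.07), sdhB (-1.39), hdeA (-1.22), glpT (-1.94), dps (-0.913), iscR (0.951), hscB (0.802) and iscX (0.781) without B alone and mdtA (1.56 and 1.95), baeS (1.11 and 0.611), argE (1.62 and 1.09), argI (1.58 and 1.16), artJ (0.936 and 0.816), iscS (1.50 and 1.20), fumA (-1.27 and -1.33), acnA (-1.14 and -0.711), nuoE (-0.775 and -0.949), nuoF (-0.542 and -1.08), nuoL (-0.909 and -0.497), rpsR (1.05 and 0.586), rplI (0.956 and 0.724), rpoH (1.06 and 1.07), osmB (1.24 and 1.12), glpF (-0.851 and -0.587) and yaaA (-0.922 and -0.773) whichever of A and B was left out. The OxyR list did not pass without A (-0.340) or B (-0.303), nor did the glycerol (-0.513) and tricarboxylic acid (-0.352) lists without B, without slide B1 the calls of cueO (0.81), nuoE (-0.499), nuoF (-0.35), nuoL (-0.332), acnA (-0.415), artJ (0.465) and argI (1.07) ended, and the count was 780 with zinc in Cy5 alone and 237 when the time was fitted alone.

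The SoxRS, cysteine, flagella, Pho, metal transport and anaerobic lists, with 25, 22, 44, 22, 22 and 34 measured genes, passed camera at none of the 5 times as first fitted. Under other settings camera called 3 of them at some time. Pho passed at 2.5 min with array medians subtracted (adjusted p = 0.0483) and with the time fitted alone (0.0338). Cysteine passed at 2.5 min with the time alone (0.0138) and without replicate B (0.00731), and at 10 min with the time alone (0.0162) and with each array as an observation (0.0363). Without replicate A it passed at 0 min (0.00893) and 30 min (0.0110). The anaerobic list passed at 0 min with letter as a fixed block (0.0463) and at 2.5 min without replicate A (0.0376). By fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, 4 of them passed at some time. These were Pho at 2.5 min (median -0.30, adjusted p = 0.0448) and 30 min (-0.18, adjusted p = 0.0173), SoxRS at 7 min (0.06, adjusted p = 0.0413), metal transport at 10 min (-0.09, adjusted p = 0.0161) and flagella at 30 min (-0.09, adjusted p = 0.0436). The members of these 6 lists named below were chosen after their values were seen, except fumC, acnA and cysH, which the rule for named genes took. The runs without 1 replicate were read for these members after their values were seen.

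In the SoxRS list 3 genes rose and 1 fell at 7 min (4 and 1 adjusted over the list alone), 2 rose and 3 fell at 10 min (3 and 3) and 1 rose and 2 fell at 30 min (1 and 2). The multidrug resistance regulator gene marA rose at 7 min (1.89 ± 0.619) and 10 min (2.40 ± 0.911) and stood at -0.48 ± 0.201 at 30 min without passing. Its operon partners marR (2.14 ± 0.413 and 2.08 ± 0.382 at 7 and 10 min) and marB (1.30 ± 0.460 at 7 min) rose too. The superoxide dismutase gene sodA fell at 7 min (-1.05 ± 0.282) and 10 min (-1.02 ± 0.0633), and fumC and acnA (-0.86 ± 0.00589) fell at 10 min. At 30 min soxS rose (1.97 ± 0.477), while fumC (-1.77 ± 0.995) and acnA (-0.92 ± 0.302) fell. Calls of marB (1.62 and 0.971), sodA at 10 min (-0.972 and -1.06) and acnA at 10 min (-0.858 and -0.866) and 30 min (-1.14 and -0.711) ended without replicate A or B. Those of marA (1.45) and sodA (-0.854) at 7 min ended without B, and fumC was lost without A at 10 min (-1.08) and without B at 30 min (-1.07).

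Flagellar genes went both ways at 10 min, with 3 higher and 2 lower, also over the list alone. There fliM (2.19 ± 1.22), cheR (1.09 ± 0.0766) and fliI (0.81 ± 0.410) rose, and flhD (-0.90 ± 0.180) and flhB (-1.03 ± 0.592) fell. At 30 min 3 fell, 2 adjusted over the list alone: the regulator genes flhD (-1.32 ± 0.105) and flhC (-1.14 ± 0.358) and the chemotaxis gene cheW (-0.93 ± 0.0123). Without replicate A or B the calls of cheR (1.14 and 1.03), fliI (1.10 and 0.516) and flhD (-0.777 and -1.03) at 10 min and of flhC (-1.39 and -0.885) and cheW (-0.940 and -0.923) at 30 min ended. Those of fliM (1.32) and flhB (-0.609) ended without B. Metal transport genes went both ways as well, with 1 higher at 2.5 min, 2 higher and 1 lower at 7 min, 2 higher and 4 lower at 10 min and 1 lower at 30 min. Adjusted over the list alone, 3 were higher and 2 lower at 7 min, with the same counts at the other times. The nickel and cobalt efflux gene rcnA (1.77 ± 0.407 and 1.23 ± 1.00 at 7 and 10 min) and its regulator gene rcnR (1.09 ± 0.138, 1.71 ± 0.467 and 0.84 ± 0.237 at 2.5, 7 and 10 min) rose. The manganese importer gene mntH fell at 7 min (-1.29 ± 0.250) and 10 min (-1.88 ± 0.116), as did nikR (-0.70 ± 0.204), phoP (-0.84 ± 0.268) and phoQ (-1.04 ± 0.256) at 10 min and phoQ at 30 min (-1.01 ± 0.217). Lost without replicate A or B were rcnR at 2.5 min (1.19 and 0.992) and 10 min (1.01 and 0.672), mntH at 7 min (-1.11 and -1.47), nikR (-0.846 and -0.558) and phoP (-0.652 and -1.03). The call of rcnA was lost at 7 min without A (1.48) and at 10 min without B (0.522, against 1.94 without A), and phoQ without B (-0.856 and -0.861 at 10 and 30 min).

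In the Pho list ugpC (-0.74 ± 0.228), ugpE (-1.76 ± 1.76) and psiF (-1.49 ± 0.879) fell at 10 min, and ugpC (-0.92 ± 0.0265) and psiF (-1.51 ± 0.412) at 30 min, with the same counts over the list alone. In the cysteine list cysH fell at 2.5 min, tauB rose at 7, 10 and 30 min (1.36 ± 0.0172, 1.63 ± 0.128 and 1.23 ± 0.850) and cysB fell at 10 and 30 min (-0.99 ± 0.278 and -1.28 ± 0.150). Adjusted over the list alone these were the same after the addition, except that 0 genes fell at 10 min, and 2 genes were lower at 0 min. Of the anaerobic list hycC, of formate hydrogenlyase, rose at 7, 10 and 30 min (1.31 ± 1.02, 1.90 ± 0.340 and 2.98 ± 0.188) and its regulator gene hycA at 10 and 30 min (1.19 ± 0.356 and 1.01 ± 0.232). Adjusted over the list alone the counts were the same, with 1 more gene higher at 2.5 min. Without replicate A or B the calls of ugpC at 10 min (-0.575 and -0.897) and 30 min (-0.935 and -0.897), tauB at 7 min (1.37 and 1.34), cysB at 10 min (-0.794 and -1.19) and 30 min (-1.18 and -1.39) and cysH at 2.5 min (-1.67 and -1.34) ended. The call of ugpE ended without A (-0.514, against -3 without B). Without B those of psiF (-0.869 and -1.22 at 10 and 30 min), tauB (1.54 and 0.627 at 10 and 30 min), hycC at 7 min (0.590, against 2.03 without A) and 10 min (1.66), and hycA (0.941 and 0.850 at 10 and 30 min) ended.

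**Figure D1:**
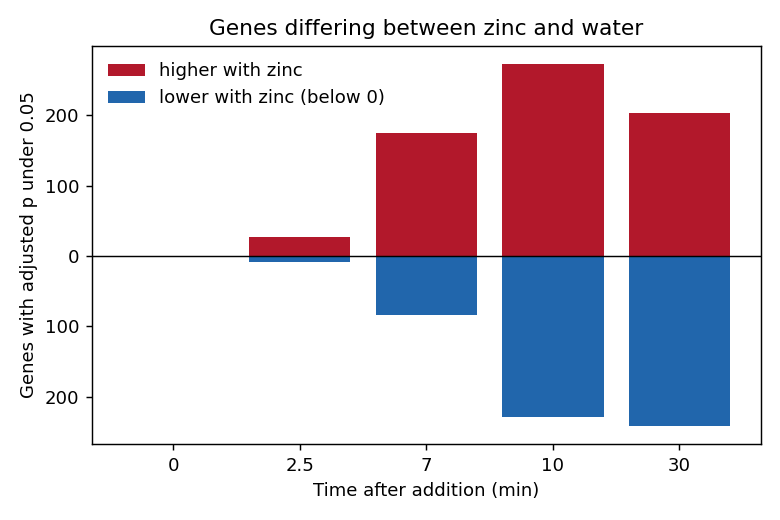
Number of genes with an adjusted p under 0.05 at each time (x axis, minutes after addition, evenly spaced and not to scale), higher with zinc drawn above 0 and lower with zinc drawn below 0. The counts go from 0 at 0 min to 502 at 10 min and 446 at 30 min.

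Relative to 0 min, the zinc to water ratio changed in 10 genes by 2.5 min (7 up, 3 down), 106 by 7 min (75 up, 31 down), 189 by 10 min (129 up, 60 down) and 153 by 30 min (93 up, 60 down). By 2.5 min, 193 genes had an unadjusted limma p under 0.05, against 214 by chance. Other settings, given with the processing, moved these counts. They were higher with each array as an observation and mostly lower in a single dye orientation. In fits of 0 and 10 min only, the count at 10 min was lower without a block and lower still with labelled letters as a block, but not with crossed letters. With the dye swaps read as already turned no change was called. zntA changed by 3.53, 4.30, 4.85 and 4.21 at the 4 later times, zinT by -6.36 and ykgM by -5.75 at 30 min, and bfd by -3.39 at 2.5 min. All 6 Zur genes passed this comparison at 10 and at 30 min, adjusted over all genes or over the list alone (medians -2.98 and -3.19; adjusted p = 0.0556 and 0.0757 with an estimated correlation). Of 11 copper genes 7, 10 and 8 rose from 0 min to 7, 10 and 30 min (9, 10 and 9 adjusted over the list alone), and of 45 Fur genes 12 fell by 7 min and 10 by 10 min (18 and 18 adjusted over the list alone, with 1 higher at 10 min). Camera called 5, 9, 9 and 12 lists over the 4 changes, of which 1, 5, 5 and 0 held with an estimated correlation. The 5 were copper, envelope stress, Fur, heat shock and zinc export at 7 and at 10 min, and the 1 was Fur at 2.5 min (median -0.60, adjusted p = 0.0355).

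The F test over the 4 changes called 167 genes. The smallest p belonged to cusF, cusB, cusC, cueO, cusA, ais, spy, ompA, cspI and mutL. The value of ompA was at -0.32 at 2.5 min, without passing, and at -2.85, -3.03 and -2.23 at 7, 10 and 30 min, and mutL at 2.58, 3.46, 3.64 and 3.51 at the 4 later times. Without replicate A of 0 min the changes to 2.5, 7, 10 and 30 min numbered 2, 47, 74 and 55 and the F test called 73, and without replicate B of 0 min they numbered 2, 55, 77 and 89 and the F test called 77. Leaving out the later replicate gave 4 at 2.5 min without B, 44 at 7 min without A, 110 at 10 min without B and 53 at 30 min without B, the F test called 95 and 107 without A and B of 2.5 min, and a variance prior with trend, robust, gave 0 (193 at an unadjusted p under 0.05), 56 and 121 changes at 2.5, 7 and 10 min and 92 by the F test.

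**Figure D2:**
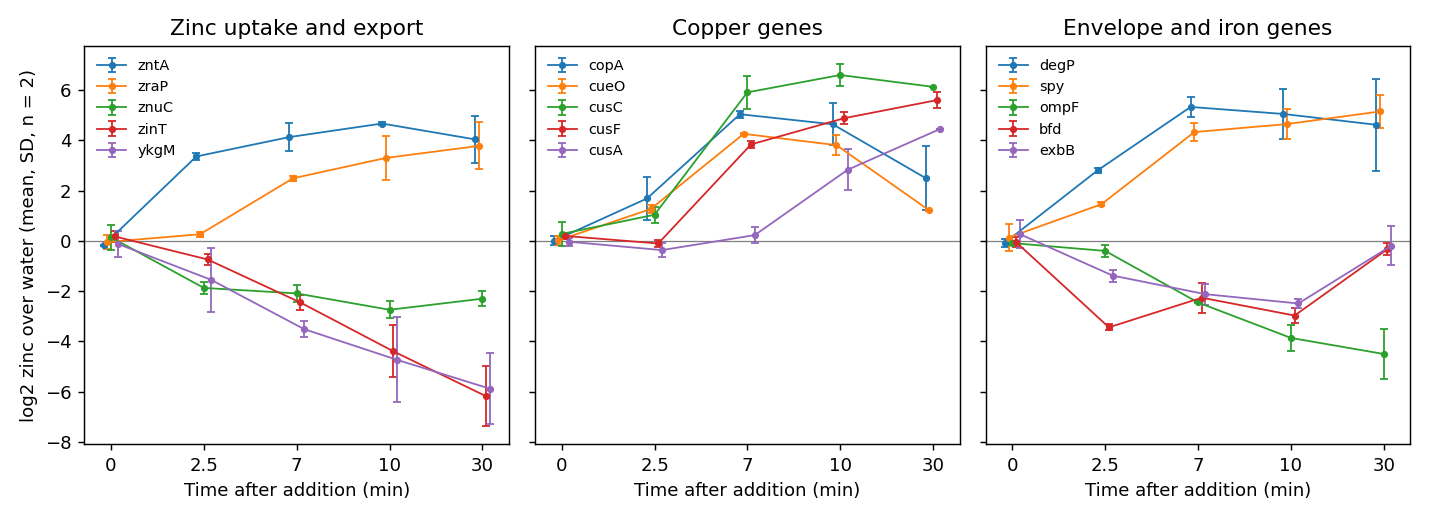
Mean log2 ratio of zinc over water with SD (n = 2) for 15 genes at each time (x axis, minutes after addition, evenly spaced and not to scale). zntA stands at 3.36 by 2.5 min, copA and cueO are lower at 30 min (2.50 and 1.21) than at 7 min (5.04 and 4.26), and bfd is at -0.33 by 30 min.

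Across times, 720 genes were called at 1 or more later times, 22 higher and 6 lower at all 4. By limma, 0 genes were called higher at one time and lower at another. Among those at all 4 were zntA, degP, fkpA, ppiA, yccA, cueO, mutL, ldtC, yncJ, ais and the lipid A genes arnB, arnC and eptA (the last pair chosen after their values were seen, and at 2.5 min lost without replicate A, 2.31 and 1.96, or B, 1.91 and 1.82). The 6 on the lower side were znuB, znuC, csgE, csgF, yrbL and 4.1.3.15. Of the genes higher at 7 and 10 min 145 were shared, against 11.2 if independent, and of those lower at 10 and 30 min 135, against 13. These numbers are no test of agreement between times. Each gene had 1 spread shared over times and the cultures were sampled repeatedly, so calls at different times were not independent.

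Differences between times were tested for the lists, with each adjusted p here from an estimated correlation. Copper genes were higher at 7 than at 2.5 min by a median of 2.30 (adjusted p = 0.0444), and Fur genes were higher at 30 than at 10 min by 0.90 (adjusted p = 0.018). Heat shock genes were lower at 30 than at 10 min by a median difference of -0.97 (adjusted p = 0.0435). From 2.5 to 30 min the Fur list differed by 0.58, the Suf and Isc list by 0.90 and the zinc export list by 0.68 (adjusted p = 0.0478 each). Of 96 such tests 41 passed with the preset correlation and 6 with both; only the 6 are given, a choice made after both counts were seen.

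**Figure D3:**
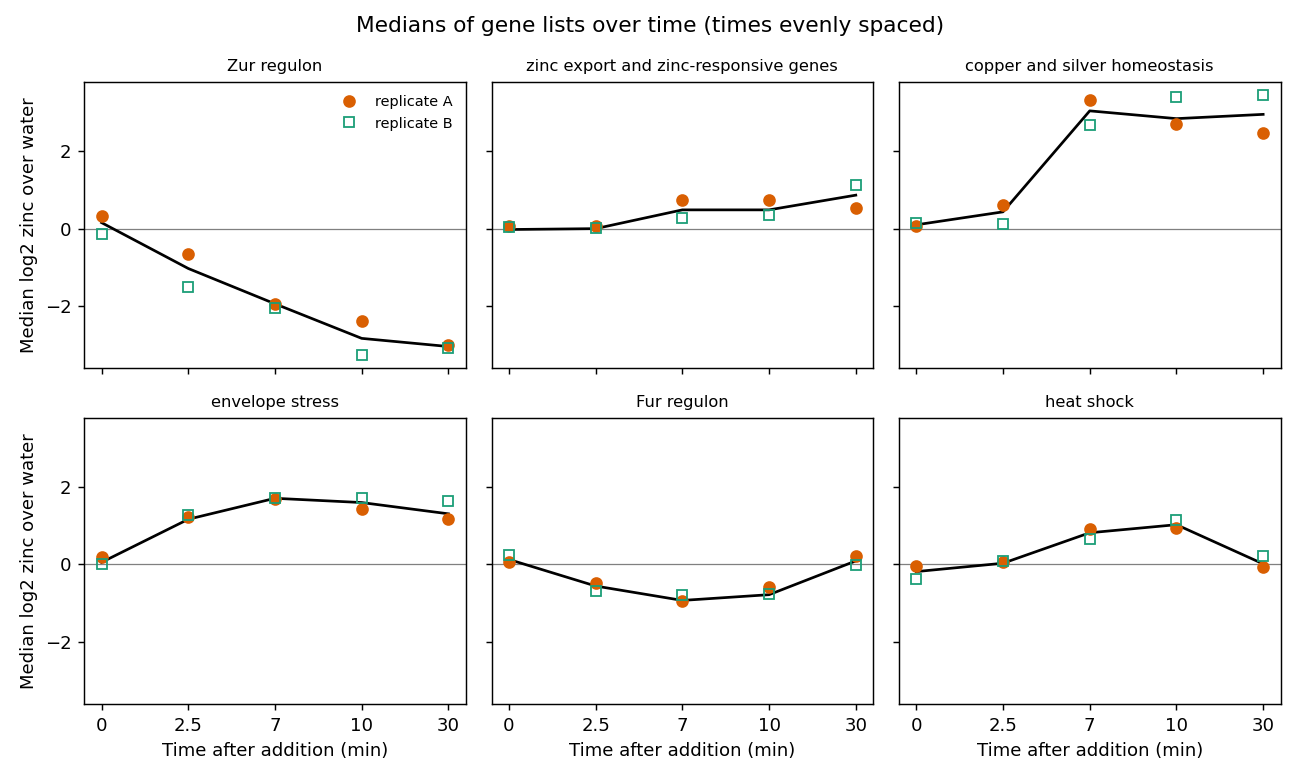
Median log2 ratio of zinc over water of 6 gene lists at each time (x axis, minutes after addition, evenly spaced and not to scale), with the line through the medians of the replicate means and points for replicates A and B. The Zur list goes to -3.04 at 30 min, the copper list to 3.03 at 7 min, and the Fur list is at -0.93 at 7 min and 0.09 at 30 min.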

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

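The comparison of copA with zntA and the test of the Fur list's change from 0 min were chosen only after the results were seen, as was the choice to list only differences between times that passed with both correlations.

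Medians of the 24 lists and the SD over all genes were compared between the slides of a time, and 4 of 125 such groups held a slide far from the others, where chance gives 6.25 at 1 in 20. The ribosomal list stood at -0.12 on slide B2 at 2.5 min, against 0.154 to 0.195 on the other slides. The OxyR list stood at -0.409 on slide B2 at 10 min, against -0.0167 to 0.132. The heat shock list stood at 0.478 on slide B1 at 30 min, against -0.059 to -0.0224. The ribosomal list stood at 0.0203 on slide A2 at 30 min, against 0.313 to 0.34.

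Of 96 differences between times tested for the lists, 41 passed camera with the preset correlation and 6 also with an estimated one. Copper genes were higher at 7 than at 2.5 min by a median of 2.3 (adjusted p = 0.0444 with an estimated correlation). Fur genes were higher at 30 min than at 10 min by 0.896 (adjusted p = 0.018) and than at 2.5 min by 0.578 (adjusted p = 0.0478). Heat shock genes differed by -0.966 between 10 and 30 min (adjusted p = 0.0435). From 2.5 to 30 min the Suf and Isc list differed by 0.897 and the zinc export list by 0.683 (adjusted p = 0.0478 each).

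The copper genes copA and cueO had lower ratios at 30 than at 7 min while cusC, cusF, cusB and cusA did not. A copA signal that came wholly from zntA transcript is argued against, since the change of copA minus that of zntA from 7 to 30 min was -2.46 (SE 0.719). A steady part of the copA signal from zntA transcript is not excluded by this comparison. An effect of 1 dye orientation or 1 replicate is argued against as well: copA and cueO fell relative to the cus genes in 4 of 4 combinations of letter and orientation, with changes of -3.67 to -2.23 against 1.17 to 2.72. That the regulons of copA and cueO and of the cus genes, which have different regulators, followed different courses may be read as a hypothesis; it was found on these data and no biological explanation was tested. Whether copper came in with the zinc remains open.

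The Fur list was lower at 7 and 10 min and back by 30 min. It was already lower at 2.5 min (median -0.56, camera adjusted p = 0.0651 with an estimated correlation). An effect of 1 dye orientation or 1 replicate is argued against by the 4 of 4 combinations of letter and orientation in which the median of 30 minus 10 min was above 0, from 0.45 to 0.986. After quantile normalization 0.869 remained. This test says little about a difference in array scale, since scale alone keeps a sign and the list's median changed sign between 10 and 30 min. Array SDs were also alike, at 0.853 to 0.95 at 10 min and 0.814 to 0.992 at 30 min. A difference between the cultures before the addition is argued against by the change from 0 to 10 min, a median of -0.852 (camera adjusted p = 8.08e-13, and 0.027 with an estimated correlation). A passing lowering of iron uptake transcripts may be biological, but this is a hypothesis from the same data, and a difference in growth or iron content between the cultures stays open, as untested.

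The mutL ratio was higher at all 4 later times. Signal from neighbouring spots with a value is argued against, reading the last 2 fields of a feature's identifier as its place in a block. The highest of these at 30 min was that of argE, at 1.36, against 3.51 for mutL (SE of the difference 0.375). Adjacent spots without a value could not be compared. Transcription of the whole neighbourhood to the level of mutL is argued against by the mean of amiB and miaA, the genes directly beside it, which was 0.43 at 30 min (SE of the difference 0.306). A smaller rise nearby is not excluded, since hflX, 3 genes away, rose at 7, 10 and 30 min (0.827, 1.04 and 0.99) and nnr, 3 genes away on the other side, at 7 min (0.758). What the mutL probe holds is not known here and was not tested, and neither was a biological explanation.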

How the results depend on the processing

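The reading of the dye swaps as already turned, the 3 slides left out singly and the letters as blocks between 0 and 10 min were chosen only after the data were seen. Counts are given in the order 0, 2.5, 7, 10 and 30 min, changes from 0 min in the order 2.5, 7, 10 and 30 min, and for each result that changed the cause was not tested unless stated. Of 48 list calls, 48 kept direction and side of the threshold under subtracted medians, scale normalization, a plain mean, letter as a fixed block, the trended prior and other filters, 47 under quantile normalization and with each time alone, 46 with each array as an observation, 36 with zinc in Cy3, 31 with zinc in Cy5, 29 with fry and 10 with an estimated correlation (calls gained are given below). Leaving out a replicate kept 78 of 96 list calls and 348 of 548 calls of named genes, where the lone remaining sample is assumed to vary like the other groups. Of 274 calls of named genes 253 were kept under quantile normalization, 247 under the trended prior, 209 with each time alone, 235 with Cy3 (6 reversed), 224 with Cy5 (3 reversed) and 261 to 274 under the others run on all of them. The table gives ratios without intensities, so signal over background is unknown, and how far weak signal limits any value cannot be said.

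Scale normalization gave 1 gene at 0 min and 69 at 2.5 min. Quantile normalization gave 1 and 81 there and 23 changes by 2.5 min. With each array as an observation the counts were 2, 92, 402 and 976 from 0 to 10 min, the changes 19, 183, 391 and 277, and the F test 448, at a correlation of -0.234 between arrays of a letter. A correlation below 0 makes the standard error of a mean smaller than for independent arrays, which can raise these counts. A single orientation cannot separate a dye effect on a gene from a zinc effect, so the counts of genes in Cy5 or Cy3 alone can hold both. With zinc in Cy5 alone there were 10, 172 and 739 genes from 0 to 7 min and 780 at 30 min, with changes of 2, 52, 80 and 90 and 74 by the F test. The copper list at 2.5 min was then -0.147, the zinc export list at 7 min 0.0122, mdtD at 7 min -0.00159, and at 30 min the OxyR list 0.113, rpsR -0.0559 and yaaA 0.192. With zinc in Cy3 alone there were 155, 194 and 924 genes from 0 to 7 min, 5, 125 and 73 changes by 2.5, 10 and 30 min, and 96 by the F test. At 2.5 min the ribosomal list was then -0.0461 and the zinc export list 0.667 (camera adjusted p = 0.014), and at 7 min the NADH dehydrogenase and ATP synthase list was 0.223 and nrdI 0.221. At 10 min nuoE was 0.153, and at 30 min the NADH dehydrogenase and ATP synthase list was 0.073, nuoE 0.064, nuoF 0.141, nuoL 0.22 and acnA 0.0409.

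With each time alone there were 195, 142 and 237 genes at 2.5, 10 and 30 min, and the zinc export list at 2.5 min (median -0.00347) passed at 0.0271. With only the times compared, 16 and 121 changed by 2.5 and 10 min. The trended, robust prior gave 16 genes at 2.5 min, 0, 56 and 121 changes by 2.5, 7 and 10 min (193 at an unadjusted p under 0.05 by limma at 2.5 min), and 92 by the F test. An adjusted p under 0.1 gave 1, 66 and 391 genes from 0 to 7 min and 253 changes by 30 min, by construction of the threshold. So did a 2-fold minimum, with 327 genes at 10 min, and an unadjusted p under 0.05 with a 2-fold minimum, with 22 and 115 genes at 0 and 2.5 min and 98, 275, 368 and 385 changes. Without 1 replicate the counts ranged from 10 to 14 at 2.5 min, 125 to 139 at 7 min and 229 to 290 at 10 min, and were 300 and 106 at 30 min without A and B, with fewer samples by construction. The changes without a replicate ranged from 2 to 11 by 2.5 min, 44 to 81 by 7 min, 74 to 137 by 10 min and 53 to 157 by 30 min, and the F test from 73 to 164. The arginine list at 0 min was -0.704 without B and 0.781 without A, the tricarboxylic acid list at 2.5 min -0.207 without B and 0.398 without A, and the nucleotide list at 7 min -1.5 without B and 0.166 without A. With an estimated correlation the adjusted p of the Zur list was 0.281, 0.0805, 0.0702 and 0.0694 from 2.5 to 30 min (medians -1.03, -1.94, -2.83 and -3.04) and that of the zinc export list 0.0528 at 30 min (0.859). By fry 5, 4, 4, 3 and 3 list calls were lost from 0 to 30 min.

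In a fit of 0 and 10 min only, 81 genes changed with labelled letters as a block and 194 with crossed letters. Leaving out the other times lowered the count without a block too, so the block alone does not account for the lower count. Leaving out slide A2 or A3 at 10 min kept 99 and 96 of 99 calls of named genes, and slide B1 at 30 min 76 of 85. The calls of grpE (0.653), rplV (0.834) and fepC (-0.69) ended without A3. Those of cueO (0.81), nuoE (-0.499), nuoF (-0.35), nuoL (-0.332), acnA (-0.415), ymgA (-0.865), artJ (0.465), argI (1.07) and iscA (0.89) ended without B1. With the dye swaps read as already turned, 1200, 826, 1437 and 937 genes differed at 0, 2.5, 7 and 30 min, while limma called 0, 0, 0 and 0 changes from 0 min and 0 by the F test (168, 125, 170, 175 and 236 at an unadjusted p under 0.05). The Zur list was then 0.0856, -0.057, 0.37 and 0.458 from 2.5 to 30 min and the zinc export list 0.4 and 0.545 at 10 and 30 min, with neither past the threshold at these times. At 7 min the zinc export list kept its call under this reading (0.868, adjusted p = 0.00507). If the arrays were not turned, this reading averages out an effect of zinc and keeps an effect of the dye.

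List calls were also gained, 53 in all, each with its adjusted p here. With each time alone 10 were: methionine at 0 min (0.0442), cysteine (0.0138), glycerol (0.0459), Pho (0.0338) and zinc export (0.0271) at 2.5 min, arginine at 7 min (0.00979), cysteine (0.0162) and NADH dehydrogenase with ATP synthase (0.0459) at 10 min, and methionine (0.00153) and nucleotide synthesis (0.0178) at 30 min. With each array as an observation 5 were: methionine at 0 min (0.0248) and 30 min (0.0223), arginine at 7 min (0.0347), and cysteine (0.0363) and Suf and Isc (0.000775) at 10 min. With letter as a fixed block 4 were: methionine at 0 min (0.0333) and 30 min (0.0258), the anaerobic list at 0 min (0.0463) and arginine at 7 min (0.0304). NADH dehydrogenase with ATP synthase passed at 0, 2.5 and 10 min with zinc in Cy5 alone (0.0200, 0.0273 and 0.000875), and with zinc in Cy3 alone zinc export at 2.5 min (0.0140), Suf and Isc at 10 min (0.00228) and methionine at 30 min (0.0320) did. A plain mean added Suf and Isc at 10 min (0.0430) and subtracted medians Pho at 2.5 min (0.0483). Fry added 6: Pho at 2.5 min (0.0448) and 30 min (0.0173), SoxRS at 7 min (0.0413), metal transport (0.0161) and Suf and Isc (0.00977) at 10 min and flagella at 30 min (0.0436). Without replicate A of the time, 5 were gained at 0 min: acid resistance (0.00709), arginine (2.9e-10), cysteine (0.00893), Fur (0.00175) and methionine (1.53e-06). At later times these were the anaerobic (0.0376), methionine (0.0376) and tricarboxylic acid (0.000808) lists at 2.5 min, acid resistance (0.0147) and methionine (0.00906) at 7 min, NADH dehydrogenase with ATP synthase at 10 min (0.0345) and cysteine at 30 min (0.0110). Without replicate B they were arginine at 0 min (1.13e-08) and 7 min (0.00356), cysteine (0.00731) and tricarboxylic acid (0.0398) at 2.5 min, Suf and Isc at 10 min (0.0442) and Fur at 30 min (0.0462). Slide A2 left out at 10 min added NADH dehydrogenase with ATP synthase (0.0437), and slide B1 left out at 30 min added methionine (0.0183).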

Other observations

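The genes of this part were put together only after their values were seen, ais and arnB being also among those the rule for named genes took, and no test of them as a set was run. The 11 measured genes were ais together with arnA, arnB, arnC, arnD, arnF, arnT, eptA, basR, basS and ugd, which belong to lipid A modification or its regulation. Of these 11 genes, 0, 4, 9, 9 and 11 rose at 0, 2.5, 7, 10 and 30 min by limma (0 at an unadjusted p under 0.05 at 0 min). Their medians were -0.04, 0.48, 2.24, 2.84 and 3.57. At 2.5 min arnA, arnD, arnT and arnF stood at -0.11, -0.13, -0.48 and -0.09 without passing. At 30 min eptA stood at 4.34 ± 0.994, arnC at 4.12 ± 0.818 and basR at 4.03 ± 1.16 (SD of both replicates), and these calls were kept without replicate A or B. At 2.5 min those of arnB (2.68 and 3.26), arnC (2.31 and 1.91) and eptA (1.96 and 1.82) ended without A or B, and at 7 min those of arnA (1.56), arnD (1.23) and basR (1.27) without B. At 30 min arnF was lost without A or B (0.730 and 0.927) and arnT without A (1.16).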
